A study of Mus musculus with 15 samples.

How the data were processed

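Ribosome-protected RNA fragments were measured in eggs and embryos of Eif4e1b knockout (KO) and heterozygous (Het) female mice of the B6D2F1 strain that carried an HA-tagged Rpl22, a protein of the large ribosomal subunit. Per the labels' protocols, about 200 eggs or zygotes, or about 100 early 2-cell embryos, were pooled for each library. The lysate was digested with 100 units of RNase I for 45 min, ribosomes were pulled down with anti-HA beads for 4 h, and libraries were made with a small-RNA kit and 22 PCR cycles. The 15 libraries formed 6 groups by stage and donor genotype, taken from the labels: M2 eggs (2 Het, 2 KO), PN5 zygotes (3 Het, 3 KO) and early 2-cell embryos (3 Het, 2 KO).

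The authors deposited 1 table of estimated counts per gene, held as whole numbers and not scaled between libraries. Per the submitters' processing notes, cutadapt, STAR 2.7.6a, StringTie 2.1.4 and deepTools 3.5.1 were used with the GRCm38 genome build. How the estimated counts were derived from the alignments, and how reads that match several genes or ribosomal RNA were handled, is not given in the sources used here. The whole numbers were taken as rounded expected counts, and a rounding step on reading leaves whole numbers unchanged. The table held 55490 genes, of which 5763 had a count in any library. Gene symbols were those of the table. Biotypes and coordinates came from the RefSeq annotation of GRCm38.p6, to which 39101 genes matched by symbol and 164 by an older symbol. The remaining 16225 had no match and took between 0.129% and 1.90% of the counts of a library. No genome sequence was used here, so reads shared between related genes or low-complexity sequence were not examined.

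Library totals ran from 93222 to 1201146 counts, and counts in protein-coding genes from 1059 to 47399. A count of 0 was read as a level under 3 counts, over the libraries of a group for folds and per library for single libraries. Such limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

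Gene tests used edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its minimum count of 10 over the 6 groups, which left 495 genes, 425 of them protein-coding. TMM factors were computed, and 1 quasi-likelihood model with robust shrinkage was fitted to all 15 libraries with the 6 group means, leaving 9 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were KO against Het at each stage, PN5 Het against M2 Het, early 2-cell Het against PN5 Het, and the difference between the KO effects of successive stages. Levels are CPM (read counts scaled to the library size) with TMM factors, given as mean ± SD over the libraries of a group. The SE of a log2 fold change was worked back from the fold change and its p in the fit, whose prior count was 0.125. It therefore adds nothing to that p.

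The rule for named genes took Eif4e1b and, among genes with a symbol that is not a clone or predicted-gene name and with at least 10 CPM in the higher group, the 8 called genes with the largest rise and the 8 with the largest fall. Where fewer than 5 were called in a direction, the 5 genes with the smallest p in that direction were named as values that did not pass. A few genes that the rule takes are not reported here. Up to 4 members with the smallest p came from each list. The tests, the rule and 20 gene lists were chosen before the data were examined: maternal-effect genes, 2-cell (zygotic genome activation) genes, chromatin remodelling complexes, pluripotency factors, cytosolic ribosomal proteins, translation factors, maternal mRNA storage and deadenylation, proteasome subunits, histone variants and chaperones, DNA methylation and histone modification enzymes, meiosis and cell cycle regulators, oxidative phosphorylation subunits, stress and unfolded protein response, zona pellucida and oocyte genes, RNA polymerase II machinery, nucleolus and ribosome biogenesis, cumulus and granulosa markers, blood and sperm markers, mitochondrially encoded mRNAs, and nuclear or structural noncoding RNAs.

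The 13 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The 7 other lists are described by their counts. Composition measures were compared by two-sided exact permutation tests on log2 values within stages or genotypes, 30 tests adjusted together. The share of nuclear noncoding RNAs sums the list of nuclear or structural noncoding RNAs without the mitochondrial rRNAs and Vaultrc5. Detection was compared with Fisher's exact test for the 18 lists with protein-coding members, adjusted together. Principal components and correlations between libraries used log2 of CPM plus 1.

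The alternatives were DESeq2 1.42.0 (Wald test), limma-voom, DESeq2 size factors, library totals only, no low-count filter, a mean of at least 50 counts, protein-coding genes only, a fit without robust shrinkage, the replicate number as a block, only the libraries of the comparison, each library left out in turn, and variance-stabilised counts. A block with the M2 knockout numbers crossed and the share of nuclear noncoding RNAs as a covariate were added after the data were seen, as were 2 comparisons averaged over genotypes or stages. Fits without a library kept the same 495 genes, a choice made after a filter on fewer libraries had let in many more genes. The model was tested on simulated data with the fitted spread and with a low dispersion of 0.1, with 100 genes changed 4-fold and 100 changed 16-fold in each comparison, and with 100 genes that changed 16-fold over the range of a covariate. The camera test was run on simulated data with the 17 tested remodellers raised 4-fold. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3.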

Results

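Ribosome-bound RNA was profiled in mouse eggs and early embryos whose mothers lacked Eif4e1b, an egg-specific relative of the cap-binding protein eIF4E, or were heterozygous for it. The question posed by the design is which maternal mRNAs are bound by ribosomes differently without the factor, from the M2 egg through the PN5 zygote to the early 2-cell embryo. The libraries were 2 Het and 2 KO of M2 eggs, 3 Het and 3 KO of PN5 zygotes, and 3 Het and 2 KO of early 2-cell embryos. Group means carry the SD over the libraries of their group, except in ranges of means and in captions. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples.

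Eif4e1b (ENSMUSG00000074895, chromosome 13, 54783994 to 54788459 on GRCm38) had 0 counts in all 15 libraries. This allows up to 0.637 CPM over the Het libraries and up to 0.846 CPM over the KO libraries (3 counts of the summed totals), and between 2.50 and 32.2 CPM in single libraries. The targeted gene therefore did not separate the genotypes at this depth, and the genotype labels could not be checked with it.

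Ribosomal RNA made up most of each library, and mRNA was a small part. Cytosolic rRNA took 58.9% to 91.9% of the counts, the 28S rRNA alone 55.5% to 80.4%, and mitochondrial rRNA 5.53% to 36.0%, with both extremes of 58.9% and 36.0% in PN5 KO replicate 3. Protein-coding mRNA took 0.696% to 5.10%. By group this share was 3.62 ± 2.09% in M2 Het (n = 2), 2.99 ± 2.05% in M2 KO (n = 2), 2.68 ± 1.50% in PN5 Het (n = 3), 3.32 ± 1.03% in PN5 KO (n = 3), 2.35 ± 2.00% in early 2-cell Het (n = 3) and 1.45 ± 0.388% in early 2-cell KO (n = 2). Library totals were 724338 ± 445129 in M2 Het, 727436 ± 479079 in M2 KO, 948113 ± 229715 in PN5 Het, 633926 ± 245708 in PN5 KO, 138720 ± 40482 in early 2-cell Het and 95314.5 ± 1785 in early 2-cell KO. Between 318 and 1679 protein-coding genes had a count in a library.

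None of the 30 tests of these measures passed after adjustment, and the design left some of them unable to pass. KO against Het within stages gave an exact permutation p of 0.895 for the protein-coding share, 0.262 for the total and 0.396 for the share of nuclear noncoding RNAs, which ran from 0.00717% to 0.733%. The early 2-cell totals (93222 to 170753) all lay below the PN5 totals (401550 to 1201146) and were 6.61-fold lower within genotypes. The exact permutation p of 0.005 is the smallest that 200 arrangements give, and over the 30 tests it comes to an adjusted p of 0.15. Within a stage the smallest possible exact permutation p is 0.333 for M2 eggs and 0.1 for the other stages. The share of nuclear noncoding RNAs in early 2-cell embryos reached that 0.1, with a mean 1.97-fold higher in KO. In PN5 zygotes it was 4.29-fold higher in KO (exact permutation p = 0.3) and in M2 eggs 1.60-fold lower (exact permutation p = 0.667), as means of log2 values.

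**Figure D1:**
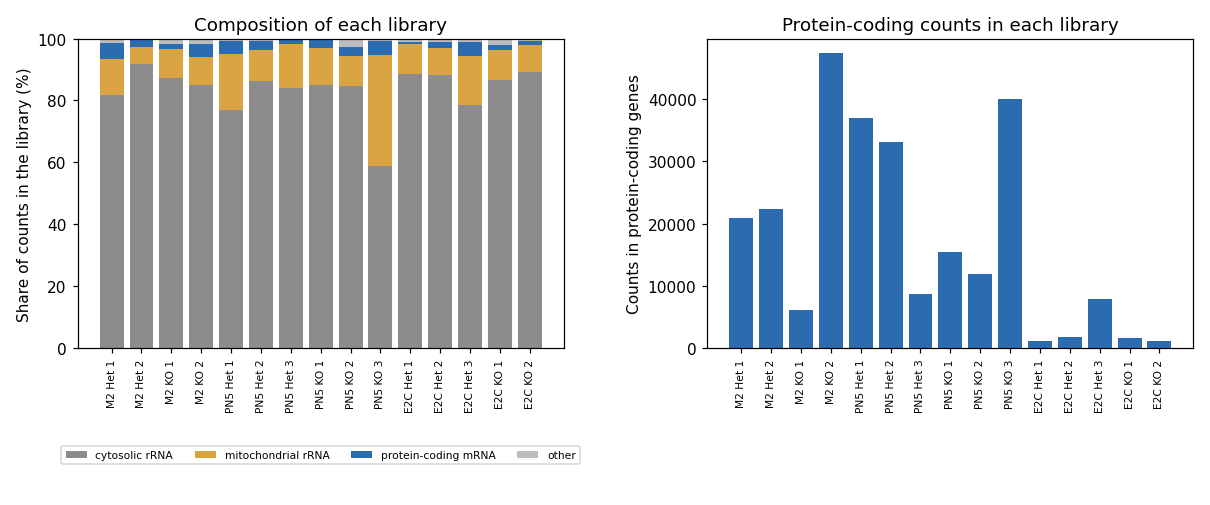
The left panel shows the share of counts (%) in each of the 15 libraries as stacked bars by RNA class, and the right panel shows the counts in protein-coding genes of the same libraries. Cytosolic rRNA takes at least 58.9% everywhere, and the protein-coding counts run from 1059 in early 2-cell (E2C) Het replicate 1 to 47399 in M2 KO replicate 2.

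Ncl, which encodes the nucleolar protein nucleolin, had the highest share of the protein-coding counts as a mean over all libraries, 6.45 ± 3.44% (n = 15), with group means from 3.21% in early 2-cell Het to 11.3% in M2 Het. In PN5 Het it was at 4.31 ± 0.542%, below Eif5b (6.20 ± 4.79%), Acbd3 (4.52 ± 2.17%) and Nexn (4.32 ± 1.65%). Over all libraries it was followed by the translation initiation factor Eif5b with 5.07 ± 2.87%, the actin-binding protein Nexn with 4.09 ± 1.97%, the cyclin-dependent kinase Cdk11b with 3.62 ± 6.27% and the histone chaperone Anp32b with 3.45 ± 2.46%. The place of Cdk11b came from early 2-cell Het libraries, where it took 14.3 ± 7.66% (n = 3), while it was at 0 in early 2-cell KO and its other group means ran from 0.598% to 1.46%. The 10 mRNAs with the highest means over the libraries together took 11.3% to 53.4% of the protein-coding counts of a library. Cdk11b had counts in 11 of the 15 libraries and Acbd3, at 1.85 ± 2.40%, in 7, so that even leading mRNAs were missing from some libraries.

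Among the fixed lists, nucleolar and ribosome biogenesis genes took 7.79 ± 3.03% of the protein-coding counts, translation factors 6.06 ± 2.75%, chromatin remodellers 4.46 ± 1.50%, histone variants and chaperones 4.12 ± 2.41%, and DNA methylation and histone modification enzymes 1.62 ± 0.579% (n = 15 each). Stress response genes took 1.12 ± 1.51%, cell cycle regulators 0.932 ± 0.994%, the RNA polymerase II machinery 0.735 ± 0.651%, cytosolic ribosomal proteins 0.707 ± 0.522%, maternal-effect genes 0.614 ± 0.449% and mRNA storage and deadenylation genes 0.421 ± 0.220%. These means pool groups that differ, and single genes held most counts of some lists. Over all libraries Ncl had 18158 of 21315 nucleolar counts and Eif5b 13434 of 15938 translation factor counts. Anp32b had 10954 of 12989 counts of the histone variants and chaperones. Canx had 4380 of 4904 stress response counts, in 5 libraries. In PN5 Het (n = 3) translation factors (6.78 ± 4.35%) and remodellers (6.60 ± 2.02%) lay above nucleolar genes (5.61 ± 0.841%), which were at 11.9 ± 0.606% in M2 Het (n = 2). In early 2-cell Het (n = 3) remodellers (3.78 ± 0.343%) lay above translation factors (3.37 ± 1.22%), and cell cycle regulators were at 2.60 ± 1.18% there and from 0.334% to 0.814% in the other groups. The lists with fewer than 3 tested members were low. Zona pellucida and oocyte genes, which include the proteins of the egg coat, took 0.218 ± 0.224%, pluripotency factors 0.117 ± 0.205%, 2-cell genes 0.113 ± 0.227% (88 counts in all), the proteasome 0.102 ± 0.125% and oxidative phosphorylation subunits 0.0327 ± 0.0512% (70 counts in all). The 2-cell genes were at 0.355 ± 0.439% in early 2-cell Het, 0.229 ± 0.199% in early 2-cell KO and 0 to 0.0266% in the egg and zygote groups. Pluripotency factors were at 0.360 ± 0.397% in early 2-cell Het and 0.0127% to 0.123% in the other groups. Cumulus and granulosa markers took 0.226 ± 0.304%, of which the steroid-producing enzyme Cyp11a1 had 561 of 857 counts. By group they took 0.544 ± 0.502% in M2 Het, 0.103 ± 0.0987% in M2 KO, 0.0783 ± 0.0587% in PN5 Het and 0.538 ± 0.368% in PN5 KO. Without Cyp11a1 these shares were 0.141 ± 0.0101%, 0.0979 ± 0.0913%, 0.0783 ± 0.0587% and 0.153 ± 0.145%. Blood and sperm markers had 1 count. Mitochondrially encoded mRNAs had 423 counts.

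Members of many of the lists were detected more often than protein-coding genes at large. At a total of at least 10 counts, 7.79% of the 21447 protein-coding genes were detected. The share was 48.5% for histone variants and chaperones, 38.7% for histone and DNA modification enzymes, 35.8% for remodellers, 33.9% for translation factors, 29.7% for stress response genes, 29.6% for ribosomal proteins, 29.4% for maternal-effect genes, 28.6% for nucleolar genes, 26.1% for mRNA storage genes, 20% for cumulus and granulosa markers, 19.6% for pluripotency factors and 17.8% for the RNA polymerase II machinery. Fisher's exact test passed for these 12 of the 18 lists with protein-coding members, with adjusted p from 1.5e-12 for the modification enzymes to 0.0251 for the cumulus and granulosa markers. It did not pass for cell cycle regulators (14.1%, adjusted p = 0.0966), zona pellucida and oocyte genes (14%, 0.187), the proteasome (10.8%, 0.561), 2-cell genes (8.16%, 0.791), oxidative phosphorylation (3.90%, 0.341) or blood and sperm markers (0%, 0.454). The test treats genes as independent, and the comparison includes genes that eggs do not express. Low-complexity reads and rRNA fragments were not examined, so these counts are not shown to be footprints on these mRNAs.

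Libraries of a group were no more alike than libraries of the other genotype. The mean correlation of log2 CPM was 0.555 ± 0.0595 within groups, 0.570 ± 0.0741 between genotypes of a stage and 0.491 ± 0.107 between stages, each across genes, which are not independent replicates. The early 2-cell libraries lay between 25.9 and 37.1 on the first principal component (30.8% of the variance), with PN5 Het replicate 3 nearest to them at 18.7. Of the egg and zygote libraries only that one (8614 protein-coding counts) and M2 KO replicate 1 (5997, at 1.31) lay above 0. They held the fewest protein-coding counts of those stages, and early 2-cell libraries held 1059 to 7795. Stage and depth are therefore not told apart on this component. The second component (12.5%) split each egg and zygote group. Deviations of Het and KO libraries with the same replicate number had correlations across genes of -0.155 in M2 eggs, -0.154, -0.324 and 0.104 in PN5 zygotes, and -0.0375 and 0.0254 in early 2-cell embryos. In a group of 2 libraries the deviations are mirror images, so M2 eggs gave a single value, 0.155 with crossed numbers. These few values cannot decide whether replicate numbers mark matched libraries. The labels do not say whether libraries were prepared together, and early 2-cell KO has no replicate 3 to set beside that of Het.

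**Figure D2:**
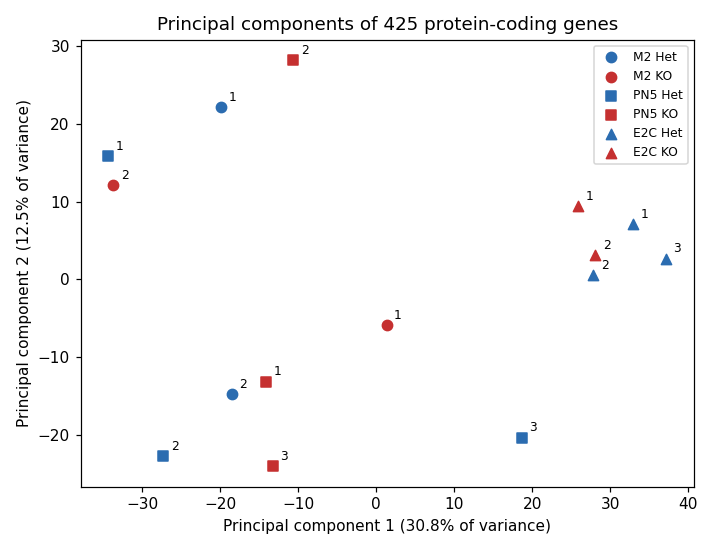
Each point is a library, numbered by replicate, on the first and second principal components of log2 CPM over 425 protein-coding genes, with Het in blue, KO in red and a symbol per stage. The early 2-cell (E2C) libraries lie from 25.9 to 37.1 on the first component, and KO and Het points of each stage are mixed.

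In M2 eggs, Las1l and Sart3 had counts in both KO libraries and none in Het. Las1l (ENSMUSG00000057421, chromosome X, 95920045 to 95956974), needed for pre-rRNA processing, was at 38.7 ± 5.32 CPM in KO (n = 2) and 0 in Het (n = 2), at least 15.9-fold higher by a floor of 3 counts over the group. The splicing factor Sart3 was at 50.1 ± 2.41 against 0 CPM (at least 20.7-fold). The nonsense-mediated decay factor Upf2 and the FACT subunit Supt16 also had 0 in Het, with counts in 1 of 2 KO libraries. In the other direction, Cyp11a1 was at 1.78 ± 2.52 CPM in KO and 122 ± 148 in Het, and Rai14 at 0 and 31.6 ± 23.4. Cyp11a1 is a cumulus and granulosa marker, so follicle cells carried over with the eggs are not told apart from the genotype for it. The chromatin genes Brd9 and Suz12 had 0 in KO and counts in 1 of 2 Het libraries.

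None of these differences passed the test. For KO against Het in M2 eggs, edgeR called 0 of 495 genes, the smallest adjusted p was 1, and 6 genes had an unadjusted p under 0.05, all higher in KO, where chance gives 24.75. DESeq2 called 2 genes, each on the counts of 1 library. These were Dek (321 counts in KO, all in replicate 2, and 0 in Het) and Nasp (0 in KO and 15 in Het, all in replicate 2). By limma-voom 0 genes were called, with 16 at unadjusted p. The groups did not overlap for 116 of 495 genes, where chance gives at most 33.3%, and less for genes with tied zeros. Among the lists, nuclear or structural noncoding RNAs came nearest (camera adjusted p = 0.149, and 0.708 with an estimated correlation). Rmrp has 2 entries among its 11 tested members. Of the 11, 8 were higher in KO, among them Rpph1 at 143 ± 1.75 against 14.2 ± 4.00 CPM. The summed share of nuclear noncoding RNAs, which leaves out the mitochondrial rRNAs and Vaultrc5 of that list, lay the other way. It was 0.198 ± 0.221% of the counts in KO and 0.392 ± 0.481% in Het. The Het mean rests on replicate 1 (0.733%), where Malat1 had 2603 counts, against 0.0519% in replicate 2. Ribosomal protein mRNAs were higher for 3 of 4 members (adjusted p = 0.169), as Rpl4 at 57.8 ± 35.1 against 24.3 ± 7.69 CPM. Without the low-count filter, over 41 members, that camera adjusted p was 0.00160. Over the other alternatives the list's adjusted p ran from 0.0767 to 0.935. The 0.935 was by fry, which does not compare a list with other genes. DNA and histone modification enzymes were lower for 9 of 12 members (adjusted p = 0.248), and the smallest adjusted p of the other lists was 0.481.

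In PN5 zygotes, the spindle-associated Nusap1 and the histone chaperone Nasp separated the genotypes in every library. Nusap1 (ENSMUSG00000027306, chromosome 2, 119618298 to 119650165) was at 30.9 ± 28.1 CPM in KO (n = 3) and 359 ± 170 in Het (n = 3), a log2 fold change of -3.51 (SE 1.19, adjusted p = 0.697 by edgeR). Nasp (ENSMUSG00000028693, chromosome 4, 116601052 to 116628676) was at 0 in KO and 58.2 ± 45.2 CPM in Het, at least 39.6-fold lower. The corepressor Ncor1 was at 0 against 102 ± 89.1 CPM, Zcchc17 at 0 against 128 ± 149 and the transcription kinase Cdk12 at 0 against 16.4 ± 17.2, each with counts in 2 of 3 Het libraries. Higher in KO were the cumulus and granulosa marker Cyp11a1 at 147 ± 169 CPM, the ribosome biogenesis factor Bms1 at 121 ± 105, the histone demethylase Kdm7a at 11.8 ± 10.3, and Rbm6 at 23.0 ± 23.4, all at 0 in Het and with counts in 2 of 3 KO libraries. Sart3, at 37.5 ± 64.9 CPM, had counts in 1. Follicle cells are again not told apart from the genotype for Cyp11a1.

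For KO against Het in PN5 zygotes, edgeR called 0 of 495 genes with a smallest adjusted p of 0.697. At an unadjusted p under 0.05 there were 35 genes, 11 higher and 24 lower in KO. DESeq2 called 2 genes, Nusap1 (-3.38, adjusted p = 0.0434) and Nasp (adjusted p = 4.5e-07), both lower in KO, and limma-voom 0 with 35 at unadjusted p. Over the alternatives the adjusted p ran from 0.0434 to 0.969 for Nusap1 and from 4.5e-07 to 0.969 for Nasp. The groups did not overlap for 29 of 495 genes, where chance gives at most 10%, and less for genes with tied zeros. No list passed: the smallest camera adjusted p was 0.842, shared by the mRNA storage genes, the histone chaperones, the RNA polymerase II machinery and the mitochondrially encoded mRNAs. The RNA polymerase II list was lower in KO for 4 of 4 members, including Taf7 at 18.2 ± 12.4 against 107 ± 55.2 CPM. Remodellers were lower for 11 of 17, among them Smarca2 at 491 ± 527 against 1347 ± 786 CPM, and nucleolar genes for 8 of 12, with a median log2 fold change of -0.86 but a mean of 0.03. Ncl itself was at 2533 ± 1375 CPM in KO and 1501 ± 449 in Het.

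In early 2-cell embryos, Cdk11b gave the widest gap between genotypes. This kinase gene (ENSMUSG00000029062, chromosome 4, 155624841 to 155649935) was at 2201 ± 1448 CPM in Het (n = 3), with 1647 counts in the 3 libraries, and at 0 in KO (n = 2), at least 187-fold lower. It was also at 0 in 1 M2 KO library and 1 PN5 Het library. Septin7, a cytoskeletal GTPase (ENSMUSG00000001833, chromosome 9, 25251991 to 25308571), was at 0 in KO and 66.3 ± 44.0 CPM in Het, at least 5.63-fold lower. The cohesin regulator Pds5b was at 0 against 42.8 ± 57.2, with 53 of 55 Het counts in replicate 3, the ribosome biogenesis factor Wdr43 at 7.98 ± 1.42 against 137 ± 148, and the remodeller Chd7 at 0 against 52.1 ± 54.7. Higher in KO were Taf3, a subunit of the transcription factor TFIID, at 124 ± 150 against 1.37 ± 2.37 CPM, with 33 of 35 KO counts in replicate 1, and Sltm at 31.9 ± 5.70 against 0. The initiation factor Eif3a, the remodeller Chd2 and the splicing-related Luc7l3 were higher in KO on the counts of 1 KO library. Without early 2-cell KO replicate 1 the log2 fold change of Luc7l3 turned to -4.62 and that of Taf3 went from 5.65 to 2.89.

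For KO against Het in early 2-cell embryos, edgeR called 0 of 495 genes, and Cdk11b had an adjusted p of 0.870. At an unadjusted p under 0.05 there were 25 genes, 17 higher and 8 lower in KO. DESeq2 called 4 genes, Hmgn5 higher and Cdk11b, Nasp and Chaf1a lower in KO, each with a library at 0, and limma-voom 0 with 11 at unadjusted p. The Het counts of Nasp (51) and of Chaf1a (107) all lay in replicate 3, so these calls rest on 1 library. The Cdk11b adjusted p was 0.00618 by DESeq2, 0.00153 without the low-count filter and 1.5e-05 in a fit of the early 2-cell libraries alone, and ran up to 1 over the other alternatives. The groups did not overlap for 50 of 495 genes, where chance gives at most 20%, and less for genes with tied zeros. KO early 2-cell libraries held 1136 and 1623 protein-coding counts, so single genes rest on few counts.

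Of the lists in early 2-cell embryos, nucleolar genes were lower in KO for 8 of 12 members and cell cycle regulators for 3 of 4, both with a camera adjusted p of 0.248 (0.481 with an estimated correlation). Without the low-count filter, over 28 members, the adjusted p of the nucleolar genes was 0.00760, and over the other alternatives it ran from 0.0774 to 0.839. Incenp, a subunit of the chromosomal passenger complex, was at 59.4 ± 5.04 CPM in KO and 293 ± 229 in Het. Maternal-effect genes were lower for 3 of 4 members (adjusted p = 0.259) and took 0.348 ± 0.118% of the protein-coding counts in KO and 1.24 ± 0.263% in Het. Smarca4 of that list was at 21.9 ± 18.3 CPM in KO and 132 ± 66.7 in Het. The smallest camera adjusted p of the remaining lists was 0.536. Taf3 was the only member of any list to pass in a KO comparison when adjusted over the list alone (adjusted p = 0.0397 by edgeR), over counts mostly in KO replicate 1, and over all genes its adjusted p was 0.892.

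**Figure D3:**
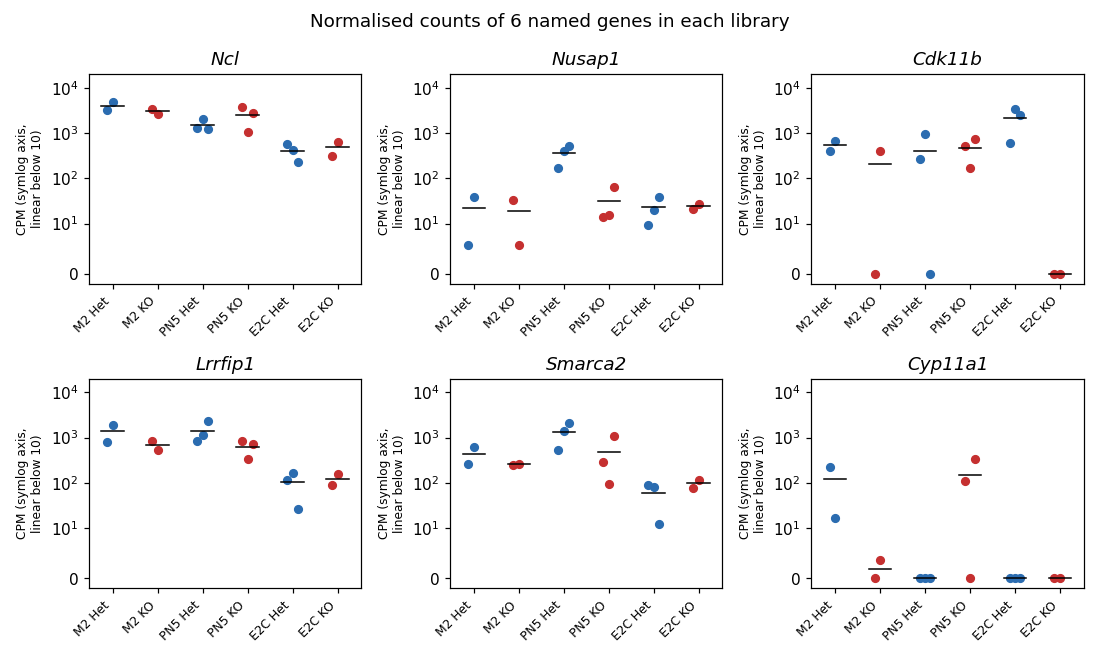
Points show CPM scaled by TMM for 6 genes in each library, on an axis that is linear below 10 and logarithmic above, with Het in blue, KO in red and a black line at the group mean. Cdk11b is at 0 in both early 2-cell (E2C) KO libraries against a mean of 2201 in Het, and Nusap1 is higher in PN5 Het (359) than in PN5 KO (30.9).

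The KO effects of the stages were compared directly. From M2 eggs to PN5 zygotes, the follicle-cell marker Cyp11a1, Rbm6, Kdm7a, Spin1 and Safb2 were among the genes with the smallest p toward a higher KO effect, and Rad50, Upf3b, Npm2 and Brd7 toward a lower one. Rad50, Upf3b, Npm2 and Brd7 had M2 KO counts in replicate 2 alone and PN5 Het counts in a single library. Safb2 had counts in a single M2 Het and a single PN5 KO library. From PN5 zygotes to early 2-cell embryos, Ncor1, Taf3, Nsrp1, Chd2 and Eif3a led toward a higher KO effect, and Cdk11b, Septin7, Tut7, Ncoa2 and Kdm7a toward a lower one. The early 2-cell KO counts of Ncor1, Nsrp1, Chd2 and Eif3a all lay in replicate 1, and those of Taf3 were 33 and 2. The genes toward a lower effect were at 0 in both early 2-cell KO libraries. For the difference between M2 and PN5, edgeR called 0 of 495 genes with 26 at an unadjusted p under 0.05 (smallest adjusted p = 0.847), and DESeq2 and limma-voom called 0 each. For the difference between PN5 and early 2-cell the counts were 0 and 26 (0.832), again with 0 by DESeq2 and by limma-voom. Across the 495 genes, which are not independent replicates, KO log2 fold changes had Pearson correlations of -0.126 between M2 and PN5, 0.0732 between M2 and early 2-cell, and -0.0478 between PN5 and early 2-cell, with Spearman values of -0.108, 0.0648 and -0.0355.

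Between M2 eggs and PN5 zygotes of Het mothers, Nusap1 and Lmo7 were higher in zygotes. Nusap1 was at 359 ± 170 CPM in PN5 (n = 3) and 21.7 ± 22.7 in M2 (n = 2), a log2 fold change of 4.04 (SE 1.45, adjusted p = 0.855 by edgeR). Lmo7 (ENSMUSG00000033060, chromosome 14, 101729928 to 101934708) was at 84.9 ± 49.2 against 0 CPM, at least 35.0-fold higher. The histone demethylase Kdm5b at 13 ± 7.24 and the pseudouridine synthase Dkc1 at 23.2 ± 21.0 had counts in all 3 zygote libraries and 0 in eggs, and the remodeller Bptf at 54.3 ± 47.1 in 2 of 3. Cyp11a1 was at 0 in zygotes and 122 ± 148 CPM in eggs, Kdm7a at 0 and 33.3 ± 25, Igsf11 at 0 and 44.6 ± 63.1, Rbm6 at 0 and 20.7 ± 29.3, and the small nucleolar RNA Snora73b at 7.70 ± 10.3 and 129 ± 119. Ncl was at 1501 ± 449 CPM in zygotes and 4058 ± 1167 in eggs.

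For PN5 Het against M2 Het, edgeR called 0 of 495 genes with a smallest adjusted p of 0.855. At an unadjusted p under 0.05 there were 17 genes, 10 higher and 7 lower in zygotes. DESeq2 called 4 genes, Nusap1, Dek and Chaf1a higher and Ncl lower in zygotes, and limma-voom 0 with 33 at unadjusted p. The groups did not overlap for 82 of 495 genes, where chance gives at most 20%, and less for genes with tied zeros. No list passed, and the smallest camera adjusted p was 0.707, for histone chaperones (6 of 9 members higher in zygotes) and ribosomal proteins (3 of 4 higher).

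Between PN5 zygotes and early 2-cell embryos of Het mothers, most tested genes were lower in the embryos after TMM scaling, with a median log2 fold change of -1.90 over the 495 genes. That median was -0.82 with DESeq2 size factors and -1.49 with library totals only, so single values stand against that shift. In the KO comparisons the median was -0.02 in M2 eggs, 0 in PN5 zygotes and 0 in early 2-cell embryos. Other scaling gave medians between -0.17 and 0.32. A gene at 0 in both groups has a fold change of 0, and the early 2-cell median was 0 under each scaling. Such a median does not show that a shift is absent. In PN5 Het against M2 Het the median was 0.10, and between -0.20 and -0.04 with other scaling.

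Below the shift from PN5 to the early 2-cell stage lay Nefh, Ddx21, Lrrfip1 and Smarca2, which did not overlap between the stages. Nefh, a neurofilament gene (ENSMUSG00000020396, chromosome 11, 4938754 to 4948064), was at 0 in embryos (n = 3) and 127 ± 59.4 CPM in zygotes (n = 3), at least 29.1-fold lower. The nucleolar helicase Ddx21 (ENSMUSG00000020075, chromosome 10, 62580247 to 62602298) was at 0 and 78.5 ± 9.38, at least 18.1-fold lower. Lrrfip1 was at 104 ± 71.8 and 1404 ± 759, a log2 fold change of -3.77 (SE 0.96), and the remodelling ATPase Smarca2 (ENSMUSG00000024921, chromosome 19, 26605073 to 26778321) at 59.8 ± 41.4 and 1347 ± 786, a log2 fold change of -4.52 (SE 1.17), each with an adjusted p of 0.139 by edgeR. The vault RNA Vaultrc5 was at 71.0 ± 58.3 and 1228 ± 949. Ncl lay at -1.88, at the median of all genes, and Eif5b at -2.59.

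Higher in early 2-cell embryos against that shift were Plcd4 at 65.0 ± 70.2 against 1.14 ± 1.98 CPM and the cytokinesis protein Anln at 61.9 ± 49.9 against 3.58 ± 3.53, both with counts in all 3 embryo libraries but 71 of 76 and 57 of 64 of them in replicate 3. The nuclear receptor coactivator Ncoa2 at 56.8 ± 86.3 against 0.998 ± 0.905, Ing4 at 56.1 ± 80.8 against 0 and the lysosomal protease Ctsl at 21.2 ± 33.2 against 0.294 ± 0.509 had counts in 2. Cell cycle regulators as a list were the nearest to a call (camera adjusted p = 0.485, higher than other genes, and 0.821 with an estimated correlation). Of 4 members 2 were higher, 1 was lower and 1 was at 0 in both groups, with Incenp at 293 ± 229 against 104 ± 55.4 CPM and Tpx2 at 65.6 ± 15.2 against 10.8 ± 9.47.

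For early 2-cell Het against PN5 Het, edgeR called 0 of 495 genes with a smallest adjusted p of 0.139. At an unadjusted p under 0.05 there were 97 genes, 18 higher and 79 lower in embryos. DESeq2 called 40 genes, 20 in each direction, 20 of them with a library at 0, and limma-voom 11, of which 2 were higher and 9 lower. The groups did not overlap for 92 of 495 genes, where chance gives at most 10%, and less for genes with tied zeros. Adjusted over the list alone, 6 members passed by edgeR, all lower in embryos: Smarca2 of the remodellers (adjusted p = 0.0239), Eif5b of the translation factors (0.0400), Taf7 (0.0155) and Taf3 (0.0161) of the RNA polymerase II machinery, Ddx21 of the nucleolar genes (0.00752) and Vaultrc5 of the noncoding RNAs (0.0312). Over all genes none of them passed, with adjusted p from 0.139 to 0.183. These tests are against no change and not against the median log2 fold change of all genes, -1.90. The log2 fold changes of the 6 lay between -2.59 for Eif5b and -8.40 for Ddx21.

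Over the 13 lists and 5 comparisons, 0 of 65 list tests were called by camera of limma, 0 with an estimated correlation and 0 by the directional test of fry. The fry test for change in either direction called 2, both for early 2-cell Het against PN5 Het: remodellers (adjusted p = 2.6e-04) and nucleolar genes (adjusted p = 0.0424). That test does not compare a list with other genes, and 13 of 17 remodellers and 6 of 12 nucleolar genes were lower in embryos, beside the shift of all genes. The median and the mean of a list had opposite signs in 15 of the 65 tests. The median did not share the camera direction in 15, a count that includes lists with a median of 0.

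The spread between libraries limited these tests. The common dispersion was 1.73, a biological coefficient of variation of 1.31. On simulated data with this spread and the same group sizes, 0 of 100 genes changed 4-fold were recovered in any comparison. Of 100 genes changed 16-fold, 3 were recovered for KO against Het in early 2-cell embryos, 3 for early 2-cell Het against PN5 Het and 0 in the other 3 comparisons. At the same spread camera called the list of 17 remodellers, raised 4-fold, in 3 of 5 comparisons. The simulated genes were drawn independently, while the estimated correlation of these remodellers in the data was 0.0729 to 0.0830. This rate may therefore be too high for the data. With a dispersion of 0.1, the share of 4-fold changes recovered was 69% for KO against Het in M2 eggs, 82% in PN5 zygotes and 31% in early 2-cell embryos. The absence of calls therefore does not show that ribosome binding was alike between genotypes. All 15 libraries were ribosome pull-downs, so a change in ribosome binding is not told apart from a change in mRNA level.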

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

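The tests of zeros beside high counts, of genotype and of the positions of libraries on the second component, of scaling and of the number of embryos per library were chosen after the results were seen, as was the test of the KO effect between M2 and early 2-cell stages.

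Sltm and Wdr43 stood out because every KO library lay on one side of the Het libraries in M2 eggs and on the other side in early 2-cell embryos. For Sltm the KO log2 fold change was -1.21 in M2 eggs and 7.11 in early 2-cell embryos, the latter resting on 8 counts. For Wdr43 it was 0.32 in M2 eggs and -4.07 in early 2-cell embryos, where KO held 2 counts. The difference itself was then tested with edgeR and did not pass, with an adjusted p of 1.00 for both genes. It called 0 of 495 genes, with 18 at an unadjusted p under 0.05, and other tools were not run on it.

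Zeros stood beside high counts within groups. Of 2425 protein-coding values with at least 10 counts expected from the other replicates, 649 were 0 (26.8%, over 282 genes), where Poisson sampling at these depths expects 0.00508. Canx, for one, was at 0 in 10 libraries and between 400 and 1261 counts in the rest. Poisson sampling leaves out the spread between samples, so depth is not excluded. The library with the highest total had the highest share of zeros in 3 of 6 groups. A small number of molecules captured before 22 PCR cycles may contribute and was not tested apart from depth. No biological explanation was tested, since the zeros lie within groups of the same stage and genotype.

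Egg and zygote libraries split on the second principal component in a way that crossed the genotypes. That libraries of the same stage and genotype lie apart is the pattern itself and no test of it. Genotype stays open as a part of it: the KO minus Het difference on the component, averaged over eggs and zygotes, was 2.75 (exact permutation p = 0.783, 120 arrangements), with a 95% interval from -34.3 to 39.8 beside an SD within groups of 23.5. Nuclear noncoding RNA in the library is a candidate explanation. Its share was 0.328% to 0.733% of the counts in the 4 egg and zygote libraries above 0 and 0.00717% to 0.147% in the 6 below, and with groups centred its log2 value followed the component (r = 0.829, exact permutation p = 0.0278, not adjusted over the 2 measures tried). For the total count the correlation was -0.466 (exact permutation p = 0.278), so depth stays open. With groups held fixed, edgeR associated 0 of 425 protein-coding genes with nuclear noncoding RNA in the library (74 at unadjusted p under 0.05) and 0 with depth (30 at unadjusted p). DESeq2 and limma-voom were not run on these associations. Both were to be excluded at 0 genes, but that bound was dropped after the 0 was seen. In simulated data for these covariates at this spread, the fit recovered 0% of 100 genes that changed 16-fold over the range of either one, so the 0 excludes neither.

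With TMM scaling, most mRNAs with a small p between the stages were lower in early 2-cell than in PN5 Het libraries. The excess depended on scaling and test: of the protein-coding genes at an unadjusted p under 0.05, 73 of 84 were lower with TMM, but 34 of 67 (50.7%) with DESeq2 size factors, 31 of 51 with library totals, 46 of 84 by DESeq2 and 49 of 68 by limma-voom. The size factors change the scaling alone and limma-voom the test alone, while DESeq2, which called 20 genes in each direction, changes both. Scaling and the test are therefore candidate explanations for the excess. Depth stays open. Of 165 genes with at least 10 counts expected over the 3 embryo libraries, 53 were at 0 in all 3, where Poisson sampling expects 5.5e-04. That bound was to exclude depth, but Poisson sampling fails within groups too (649 zeros), so lower depth or capture is not excluded. In KO libraries the 73 genes lower in Het had a median log2 fold change of -2.41, beside -1.91 for all 425 protein-coding genes, so the KO libraries show the shift of all genes as well. Noise of the Het libraries remains a candidate explanation only for the part below that shift, since the difference of -0.50 lies just inside the limit of 0.5 set beforehand for noise. Of those 73 genes, 44 lay below the all-gene median in KO, 17 were lower at an unadjusted p under 0.05 and 29 were at 0 in both early 2-cell KO libraries, as were 189 of all 425. The number of embryos per library (100 against 200) cannot be told apart from the stage, and the stage itself stays open as a biological explanation.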

How the results depend on the processing

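The block with crossed M2 numbers and the nuclear noncoding RNA covariate were chosen after the data were seen. The counts of called genes moved with the test and the filter. DESeq2 called 2 genes for KO against Het in M2 eggs, 2 in PN5 zygotes, 4 in early 2-cell embryos, 4 for PN5 Het against M2 Het and 40 for early 2-cell Het against PN5 Het. A library at 0 was part of 2, 1, 4, 2 and 20 of these calls. Without the low-count filter (5763 genes) edgeR called 1 gene in early 2-cell KO against Het (Cdk11b), 3 for early 2-cell Het against PN5 Het (Ice1, Zrsr2, Dek) and 2 for the difference of the KO effects between PN5 and early 2-cell (Ncor1, Cdk11b), and camera called 7 of its list tests, which then include genes with few counts. For KO against Het these were ribosomal proteins in M2 eggs (higher in KO, adjusted p = 0.00160), zona pellucida and oocyte genes in PN5 zygotes (higher, 0.0344) and in early 2-cell embryos (lower, 0.00520), and nuclear or structural noncoding RNAs (higher, 0.00520) and nucleolar genes (lower, 0.00760) in early 2-cell embryos. For early 2-cell Het against PN5 Het they were zona pellucida and oocyte genes (higher in embryos, 0.00353) and remodellers (lower, 0.0463). Over the other alternatives, fry included, the adjusted p ran from 0.0767 to 0.935 for the ribosomal proteins, 0.0774 to 0.934 for the noncoding RNAs, 0.0774 to 0.839 for the nucleolar genes and 0.193 to 0.979 for the remodellers, and the zona pellucida list had fewer than 3 tested members. The 0.935 and the 0.193 were by fry, which does not compare a list with other genes. For early 2-cell Het against PN5 Het, a mean of at least 50 counts (63 genes) gave 3 calls, limma-voom 11 and a fit of those libraries alone 4. A fit of the early 2-cell libraries alone called 1 gene for KO against Het. Leaving out each library gave 0 to 1 calls for early 2-cell KO against Het and 0 to 1 for early 2-cell Het against PN5 Het, the 1 in both without early 2-cell Het replicate 2 (Top1), and 0 in the other comparisons; a lone library is then assumed to vary like the other groups. The replicate block gave 0 calls in edgeR in the 7 comparisons, with 6 to 72 genes at an unadjusted p under 0.05, and so did the crossed block (9 to 31) and the covariate (16 to 100).

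Of 1208 values of named genes under the alternatives, in 70 pairs of gene and comparison, 1172 kept their direction and side of the threshold, 25 newly passed, 9 went to a fold change of 0 and 2 reversed. The 9 left no difference without 1 library: Supt16 and Upf2 (KO against Het, M2) without M2 KO replicate 2, Brd9 (KO against Het, M2) and Igsf11 (PN5 Het against M2 Het) without M2 Het replicate 1, Suz12 (KO against Het, M2) and Rbm6 (PN5 Het against M2 Het) without M2 Het replicate 2, Sart3 (KO against Het, PN5) without PN5 KO replicate 1, and Chd2 and Eif3a (KO against Het, early 2-cell) without early 2-cell KO replicate 1. Without early 2-cell KO replicate 1, which held all KO counts of the gene, Luc7l3 went from a fold change above 0 to -4.62 (up to 9.13 without other libraries), and the Eif3a difference of KO effects between PN5 and early 2-cell to -0.24 (up to 9.96). With at least 50 counts the correlation of the KO effects of PN5 and early 2-cell was 0.137, and with variance-stabilised counts the correlation within groups was 0.639; the cause was not tested for these or for the other calls that moved. DESeq2 size factors, library totals, protein-coding genes and a fit without robust shrinkage gave 0 calls by edgeR in all 7 comparisons, with 6 to 94 genes at an unadjusted p under 0.05. The camera list tests and the directional fry test stayed at 0 calls under the alternatives other than no filter, while the fry test for change in either direction called 2. Camera was not run on DESeq2. The depth of 1059 to 7795 protein-coding counts per early 2-cell library limits every comparison with that stage.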

Other observations

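The averaged comparisons were chosen after the single comparisons had been seen, and the splits were counted by genes at an unadjusted p after the counts of called genes had been seen to be 0.

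Averaged over genotypes, Nefh, Ddx21, Cenpe and AC161374.3 were lower in early 2-cell embryos than in PN5 zygotes and passed the edgeR test. The log2 fold changes were -7.14 for Nefh, -7.85 for Ddx21, -8.82 for the kinetochore motor gene Cenpe and -8.42 for AC161374.3, with adjusted p from 0.0406 to 0.0491, beside an all-gene median of -2.01. Eif5b lay at -2.36 and Smarca2 at -3.43, each with an adjusted p of 0.0613. As many as 4 called genes came up in 7 of 100 splits of the libraries within genotypes, the real one included, and the highest of the other splits gave 4, so chance is not excluded. At an unadjusted p under 0.05 there were 122 genes, 4 of the 100 splits gave as many, the real one included, and the highest other split gave 122. The shares of the 2 counts thus lie on either side of 0.05. The random splits were not kept from repeating the real labels, so the shares may count the real split again.

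Averaged over stages, Nasp had the smallest p for KO against Het (log2 fold change -7.08), followed by Cdk11b (-4.79), Las1l (4.75), Ddx24 (-3.95) and Septin7 (-2.80). edgeR called 0 of 495 genes with 20 at an unadjusted p under 0.05, and DESeq2 and limma-voom were not run on this average. At the unadjusted p, 51 of 100 splits within stages, the real one included, gave as many genes and the highest of the others gave 46, so chance is not excluded.

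For KO against Het in PN5 zygotes, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 35 genes at an unadjusted p under 0.05 (0 called by edgeR), 7 of the 10 gave as many, and the highest of the others gave 66. For early 2-cell Het against PN5 Het, 10 splits are likewise too few: the real one gave 97 genes at an unadjusted p under 0.05, 1 of the 10 gave as many, and the highest of the others gave 86.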
